A study of Mus musculus with 36 samples.

How the data were processed

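Gene expression was measured on 36 one-colour mouse arrays hybridised with amplified, biotin-labelled cDNA from sorted blood progenitors of C57BL6 mice, per the labels. The deposited table holds log2 expression values made with RMA, which corrects background, normalizes between arrays and summarises probes, per the submitters' processing notes. The log base is not stated; the values behave as log2 and are read as such, and no RMA version is given in the sources used here. The labels fall into 2 styles. The 15 arrays of deposit set 1, in 5 populations, carry a tissue and a remark that each sample is a pool of several mice; the 21 arrays of deposit set 2, in 7 populations, carry neither. Array medians ran from 5.12 to 5.22 in set 1 and from 5.84 to 5.95 in set 2, and the lower quartiles from 3.55 to 3.65 and from 4.41 to 4.67, so the sets were normalized apart. Levels are therefore compared only within a set, and every comparison across arrays carries the set as a term.

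The table has 45101 probe sets, of which 64 are controls. The annotation used here names exactly 1 gene for 34945 probe sets and several genes for 932, and lists no gene for 9160. Symbols were checked against a current gene table through the gene identifier; 204 probe sets found no match and kept their symbol, and 0 symbols changed. For each gene the probe set with the highest mean over all arrays stood for it, among those with 1 gene, which left 18193 genes. No value was missing and no column was left out. Of these genes 9010 had several probe sets. None of the 111 genes chosen by the rule for named genes had another probe set called in the opposite direction in its comparison. Other genes named in the text were not checked in this way. Arrays give no read depth; their number limits the precision.

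Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in a single model of population and deposit set over all 36 arrays. The 2 populations of a comparison shared the spread estimated over all 8. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 and its difference at least 1 on the log2 scale, which is 2-fold. Where the arrays of both populations lie in the same set, levels or differences within that set are given beside the fitted difference for part of the genes. For the others the fitted difference is given alone. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables, distances and plots.

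The comparisons, the model, the lists and the rule for named genes were fixed before the data were examined. In each comparison the text draws on the 6 called genes with the largest rise and the 6 with the largest fall among those whose arrays did not overlap between the populations, on the 2 called members of each list with the largest difference (or, with none called, the 2 with the smallest p), and on the genes behind the sorting gates. The first part of this rule asks for arrays that do not overlap, so genes named by it separate the populations array by array by construction; those named through lists and gates need not. Other members of a list are named as examples of its count. Genes named outside this rule are said to be so.

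The 18 lists hold 308 distinct genes, 24 of them not measured here. They cover stem cells, megakaryocyte and erythroid cells, granulocytes and monocytes, early lymphoid progenitors, the B lineage, the T lineage, Notch receptors and targets, the cell cycle, homing and adhesion, natural killer and innate lymphoid cells, dendritic cells, macrophages, stroma and endothelium, thymic epithelium, double-positive thymocytes, red cells, immediate early and heat shock genes, and fetal and neonatal genes. For each list the text gives the members called over all genes and the count adjusted over the list alone. Lists were also tested with camera, which asks whether a list's genes stand apart from the other genes, at a preset inter-gene correlation of 0.01. Its p-values were Benjamini-Hochberg adjusted over the 144 tests of lists and comparisons. Of these, 57 passed 0.05 at the preset correlation and 37 with a correlation estimated from the data.

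The distance between arrays was the root mean square of the log2 differences over all genes, within set 2, with an exact two-sided permutation test of the population labels. The fitting steps were tested on simulated data with 200 changed genes. For each comparison they recovered 86.6% to 97% of genes changed by 1.5 on the log2 scale and 97% to 100% of those changed by 2 or 3, with at most 3 false calls among 18193 genes. The simulated noise was independent between genes, with 1 spread per gene for all populations and the same set effect in each. The real arrays need not meet these conditions, so the simulation can understate their false calls. Alternatives to the set term, the arrays in the fit, the scaling, the choice of probe set, the filter on low values, the fold threshold and the array weights were run, as well as leaving out each array in turn. Neither centring each array on its median nor quantile normalization over all arrays moved the median gene of a comparison by more than 0.06 on the log2 scale. Under each alternative the camera p-values were adjusted over the same 144 tests, those of the refitted comparisons replacing their first values. After the data were seen, 2 further alternatives were added. The first took off the squared distance from ETP the part that the spread within CLP and within LSK adds. The second left out the 7 marrow arrays with late granulocyte transcripts, whose mean over 7 such genes lay more than 0.5 on the log2 scale above every thymic array of the same set.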

Results

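The arrays measured mRNA in 8 sorted populations of early blood and thymus development. Haematopoietic stem cells (LSKFlt3-CD48-CD150+, here HSC) were on 6 arrays, and the bone marrow population LSKFlt3hi IL7R+ (here LSK), labelled as thymic seeding progenitors, on 6. Early thymic progenitors with high Flt3 (ETPFlt3hi, here ETP) and DN3 thymocytes were on 6 arrays each. Each of these 4 populations had 3 arrays in deposit set 1 and 3 in set 2. DN2Kit+ thymocytes (here DN2) were on 3 arrays, all in set 1. Common lymphoid progenitors (CLP, labelled as a putative thymus seeding progenitor) were on 4 arrays, adult early thymic progenitors on 2 and B cell progenitors (pro-B) on 3, all in set 2. Every array carries an age label of 1 week, the arrays titled adult included, and a sex label of both sexes. Arrays give no depth, and their number limits the precision. The correlation between arrays of a population within a set averaged from 0.970 for HSC in set 2 to 0.990 for DN2. Each array lay nearest to another of its own population, except the 4 CLP arrays, all of which lay nearest to an LSK array. In set 2 the CLP arrays also lay further from one another (mean distance 0.445) than the LSK arrays did (0.334).

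**Figure D1:**
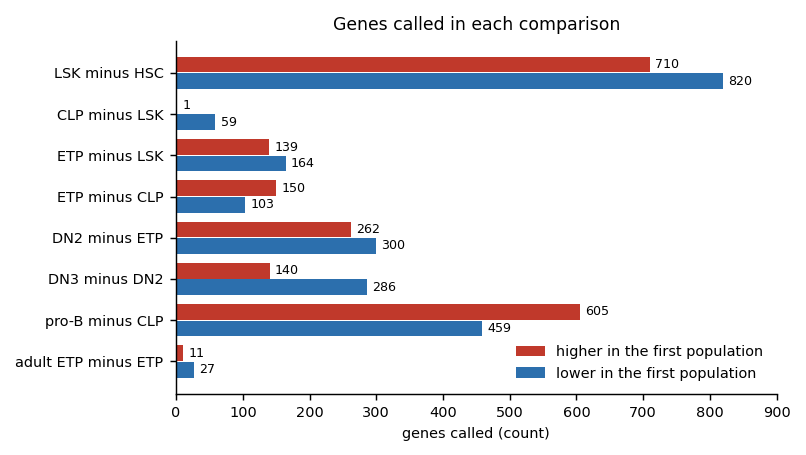
Bars give the number of genes called higher or lower in the first population of each of the 8 comparisons (horizontal axis, count of 18193 genes tested). LSK minus HSC called 710 higher and 820 lower genes, and CLP minus LSK 1 and 59.

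The step from HSC to LSK asked what sets the marrow population apart from stem cells. Early lymphoid genes were higher in LSK. Dntt, the terminal transferase of V(D)J recombination, was higher by 8.04 ± 0.23 (SE) on the log2 scale (adjusted p = 2.32e-22). It stood at 12.18 ± 0.15 (SD, n = 3) against 4.39 ± 0.46 (n = 3) in set 1, and at 12.83 ± 0.06 (n = 3) against 4.54 ± 0.16 (n = 3) in set 2. Il7r, the receptor for interleukin 7 and part of the LSK gate, rose by 7.06 ± 0.19 (adjusted p = 6.78e-23), and the recombinase gene Rag1 by 6.74 ± 0.24 (adjusted p = 6.14e-20). The early lymphoid list had 11 of 16 measured members higher and 0 lower, the same count adjusted over the list alone (camera adjusted p = 8.61e-19). Flt3, which the LSK gate takes high and the HSC gate excludes, stood at 4.77, and Satb1, a chromatin organiser, at 3.54. Stem cell genes fell: 18 of 20 measured members were lower and 0 higher, also when adjusted over the list alone (camera adjusted p = 3.31e-32). Tek, the angiopoietin receptor of quiescent stem cells, was lower by a log2 difference of -6.11 ± 0.27 (adjusted p = 5.17e-18). Mecom, a transcription factor of stem cells, was lower by -5.03, and Slamf1, which encodes CD150 of the HSC gate, by -3.48. The collagen IV genes Col4a1 and Col4a2 (-5.04 and -4.81) and the growth factor adaptor Grb10 (-5.37) were also lower. Cd48, which the HSC gate excludes, was higher by 5.53 ± 0.39, with 6.84 in set 1 and 4.21 in set 2. In set 2, HSC replicate 5 reached 7.47.

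The megakaryocyte and erythroid list had 7 of 19 measured members lower and 0 higher in LSK, also adjusted over the list alone (camera adjusted p = 1.19e-06), among them Vwf (-3.85) and the platelet factor Pf4 (-2.33). The cell cycle list had 14 of 28 members higher and 0 lower, the same adjusted over the list alone (camera adjusted p = 1.36e-19), with the mitotic kinases Bub1 at 2.62 and Aurkb at 2.14. These 4 lists also passed with an estimated correlation. Granulocyte and monocyte genes went both ways: 7 of 23 were higher and 4 lower, also adjusted over the list alone, with a median of -0.02 and a mean of 0.64 and no call for the list (camera adjusted p = 0.242). Mpo, the granule peroxidase of myeloid progenitors, was higher by 5.11 ± 0.64 (adjusted p = 1.47e-07), with an SD of 3.12 over the HSC arrays of set 1 and 2.20 over those of set 2, and the surface receptor Cd33 by 4.09. Late granulocyte transcripts were raised in 3 of these arrays: their mean was 5.21 and 4.43 in LSK replicates 1 and 3 and 6.13 in HSC replicate 5, against at most 3.58 and 4.84 in thymic arrays of the same set. In all, limma called 1530 genes, 710 higher and 820 lower; within set 1 it called 1496 and within set 2 1606. The balance turned to 791 higher and 762 lower with each array centred, 620 and 402 without the genes of low mean, and 2643 and 2106 without a fold threshold.

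**Figure D2:**
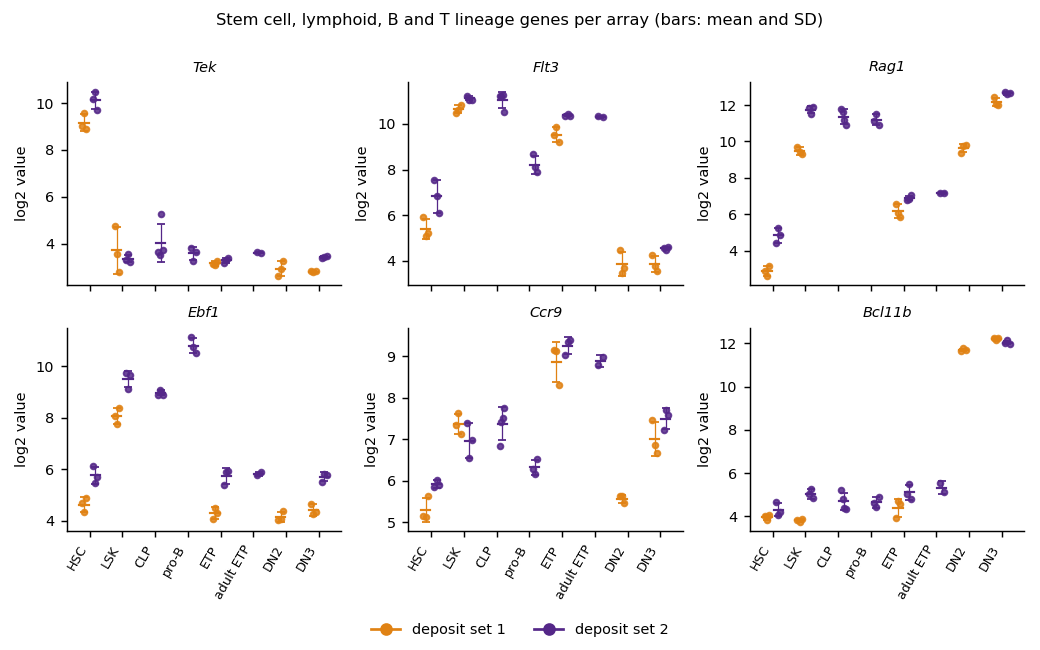
Dots are single arrays (vertical axis, log2 value) by population (horizontal axis), with the mean and SD in each deposit set. Tek falls between HSC and LSK, Ebf1 is highest in pro-B, Ccr9 is highest in ETP, and Bcl11b is at 11.70 in DN2 against 4.39 in ETP of set 1.

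CLP and LSK are both labelled as thymus seeding candidates, and the comparison asked how they differ. Genes of cell division were lower in CLP. Ube2c, an enzyme that marks mitotic cyclins for destruction, was lower by a log2 difference of -1.93 ± 0.19 (adjusted p = 9.87e-08). It stood at 9.57 ± 0.38 (SD, n = 4) in CLP and 11.60 ± 0.11 (n = 3) in LSK of set 2. The spindle genes Nusap1 (-1.68, adjusted p = 5.17e-07), Aurka (-1.68, adjusted p = 2.21e-06), Aspm (-1.60, adjusted p = 2.75e-05) and Prc1 (-1.55, adjusted p = 4.53e-05) were lower as well. Within set 2 these were -1.68, -1.68, -1.65 and -1.60. With these 2 populations alone in the model and no set term all 5 genes lost their call, with adjusted p from 0.0553 for Aspm to 0.163 for Nusap1. Aurka was at -0.85, under 2-fold, with the mean of its probe sets, and Aspm and Prc1 had adjusted p = 0.0542 and 0.0882 when tested against 1.5-fold with treat. The cell cycle list had 7 of 28 members lower and 0 higher, also adjusted over the list alone. Its median was -0.38 over both sets and -0.33 within set 2 (camera adjusted p = 4.91e-13, and 0.000228 with an estimated correlation). Of the B lineage list, 1 of 22 members was called, also adjusted over the list alone: Igll1, the surrogate light chain gene, was lower by -1.43 ± 0.28 (adjusted p = 0.00471) and by -1.75 within set 2. The Igll1 call was lost with the mean of its probe sets (-0.61, adjusted p = 0.21) and without the set term (-0.87, adjusted p = 0.223). The B lineage list was lower at the preset correlation (median -0.27, and -0.58 within set 2, camera adjusted p = 0.00917), with adjusted p = 0.378 at an estimated correlation. Leaving out CLP replicate 3 or 4 or LSK replicate 4, 5 or 6 took its adjusted p to 0.0953 to 0.138. From set 1 to set 2 the B lineage list moved up by a median of 0.67 more in LSK than in HSC. The fitted median thus depends on which LSK arrays CLP is set against, and only set 2 holds CLP.

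No member of the early lymphoid (16), granulocyte and monocyte (23), T lineage (22) or stem cell (20) lists was called between CLP and LSK, over all genes or adjusted over the list alone. Their medians were -0.05, 0.09, 0.04 and 0.23, and the camera adjusted p-values 0.575, 0.338, 0.712 and 0.022; for stem cell genes adjusted p = 0.378 with an estimated correlation. Leaving out CLP replicate 3 or LSK replicate 5 or 6 took the stem cell p to 0.492, 0.0778 and 0.128. The granulocyte and monocyte list was called higher within set 2 (median 0.21, camera adjusted p = 0.00395) and after quantile normalization (0.21, 0.0139). Values of members that came nearest included Fgd5 at 0.75 (adjusted p = 0.296), Cebpa at -0.78 (adjusted p = 0.275), Ms4a6c at 0.81 (adjusted p = 0.219) and Cd247 at -0.40 (adjusted p = 0.235). Kit, the stem cell factor receptor that classical gates set lower on CLP, differed by -0.17 ± 0.27 (adjusted p = 0.86) in the fit over both sets. Within set 2 it stood at 8.70 ± 0.37 (SD, n = 4) in CLP against 8.69 ± 0.06 (n = 3) in LSK. The only gene called higher was Mmp9, a gelatinase of neutrophil granules, by 1.38 ± 0.31 (adjusted p = 0.023), and by 1.56 within set 2 (adjusted p = 0.197). Without CLP replicate 1, at 8.69, its difference was 0.74, under 2-fold. Leaving out LSK replicate 4 or 6 took its adjusted p to 0.0956 or 0.0647, the mean of its probe sets to 0.0521, and these 2 populations alone to 0.178. Fam72a, lower by -1.71 ± 0.34 (adjusted p = 0.0059), was lowest on CLP replicate 3 (5.24), and its call was lost without the set term (-1.37, adjusted p = 0.168). Late granulocyte transcripts averaged 6.86 and 5.72 on CLP replicates 1 and 2 and 4.43 to 4.75 on the LSK arrays of set 2. Of the 60 called genes 59 were lower in CLP; within set 2 59 were called, 46 of them shared. There were 11 called when the model held these 2 populations alone, without the set term, and 38 when all arrays were kept without it.

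**Figure D3:**
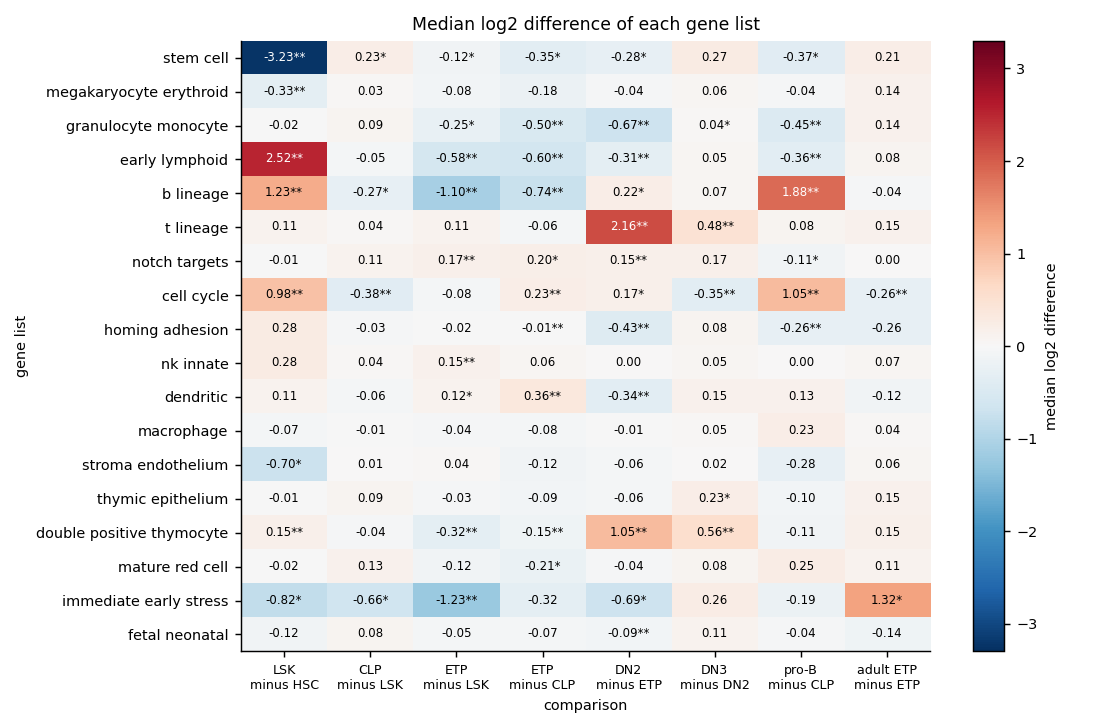
Each cell gives the median log2 difference of a list (vertical axis) in a comparison (horizontal axis); 1 star marks a camera adjusted p under 0.05 at the preset correlation and a second star one that also passes with an estimated correlation. The T lineage list stands at 2.16 in DN2 minus ETP and the stem cell list at -3.23 in LSK minus HSC.

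ETP are the earliest thymic population here, and they were set against each marrow candidate. B lineage genes were lower in ETP than in LSK. Vpreb1, a surrogate light chain gene, fell by 4.14 on the log2 scale (SE 0.49, adjusted p = 4.03e-07). It stood at 6.69 ± 0.93 (SD, n = 3) in ETP against 9.91 ± 0.43 (n = 3) in LSK of set 1. In set 2 it stood at 6.23 ± 1.17 (n = 3) against 11.28 ± 0.12 (n = 3). Rag1 fell by 4.08 (SE 0.24, adjusted p = 1.64e-13) and the octamer coactivator Pou2af1 by 3.92 (SE 0.45, adjusted p = 1.88e-07). Rag1 stood at 6.17 in ETP against 9.48 in LSK of set 1, and at 6.91 against 11.75 in set 2. From set 1 to set 2 Rag1 moved up by 1.54 and Pou2af1 by 3.06 more in LSK than in ETP (interaction adjusted p = 0.0736 and 0.149). The B lineage list had 11 of 22 members lower and 1 higher, the same adjusted over the list alone (camera adjusted p = 2e-25, and 0.000251 with an estimated correlation). Its median was -0.50 within set 1 and -1.32 within set 2. The list's level in LSK itself differed between the sets. From set 1 to set 2 it moved up by a median of 0.89 more in LSK than in ETP (camera adjusted p = 2.2e-17, and 0.000187 with an estimated correlation). The member that rose, Bst1 (2.61), encodes the stromal cell surface enzyme CD157. Il7r (-1.84), for which LSK were sorted, and Dntt (-2.09), both high in LSK, were lower in ETP.

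Genes higher in ETP than in LSK included Fasl, the death ligand of T and natural killer cells, by 4.87 ± 0.21 (adjusted p = 2.15e-17). It stood at 8.56 ± 0.09 (SD, n = 3) against 3.49 ± 0.18 (n = 3) in set 1, and at 8.39 ± 0.28 (n = 3) against 3.72 ± 0.27 (n = 3) in set 2. Trbv1, a T cell receptor beta segment, rose by 3.19 and the calcium-binding S100a4 by 2.82. Of the homing and adhesion list 2 of 16 members were higher and 1 lower, also adjusted over the list alone. The chemokine receptor Ccr9, which guides cells to the thymus, rose by 1.90 ± 0.19 (adjusted p = 1.69e-08) and the integrin Itgb7 by 1.96 ± 0.21 (adjusted p = 9.32e-08), while S1pr1 fell by 1.04. The list as a whole was not called (camera adjusted p = 0.212; median -0.02, mean 0.19), but it was called within set 2 (median 0.053, camera adjusted p = 0.0108), without the genes of low mean (0.12, 0.0193) and without the set term (-0.02, 0.0379). Notch receptors and targets had 3 of 15 members higher and 0 lower, also adjusted over the list alone (camera adjusted p = 0.000285, and 0.0148 with an estimated correlation): Deptor at 2.39, the Notch feedback gene Nrarp at 1.32 and Il2ra at 1.09. Nrarp stood at 1.93 within set 1 and 0.71 within set 2 (adjusted p = 0.634), and at 0.73 with its most variable probe set (adjusted p = 0.399). Of the T lineage list 3 of 22 members were higher (Thy1 2.35, Gata3 1.16, Il2ra) and 2 lower (Rag1, Ets1 at -1.41), or 3 and 3 adjusted over the list alone. The list was not called (camera adjusted p = 0.55; median 0.11, mean -0.03).

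The granulocyte and monocyte list had 4 of 23 members lower and 2 higher in ETP than in LSK, also adjusted over the list alone, with Irf8 at -1.95 and Cebpa at -1.51 (camera adjusted p = 0.00545, and 0.324 within set 2; adjusted p = 0.0561 with an estimated correlation). Csf1r, the macrophage colony stimulating factor receptor, was higher by 1.63 ± 0.43 (adjusted p = 0.0246), and within set 1 its adjusted p was 0.519. With the mean of its probe sets the difference was 0.83, under 2-fold. Leaving out ETP replicate 1 or 2 or LSK replicate 2, 3, 5 or 6 took its adjusted p to 0.0536 to 0.0899. In set 1 the late granulocyte mean was 5.21 and 4.43 on LSK replicates 1 and 3, and at most 3.58 on the ETP arrays. The immediate early gene Fosb was lower by -3.89 ± 0.72, by -4.97 within set 1 and by -2.81 within set 2 (adjusted p = 0.177). In all 303 genes were called, 139 higher and 164 lower; within the sets 274 and 256 were called.

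Against CLP, Fasl was higher in ETP by 4.74 ± 0.24 (adjusted p = 5.08e-15), Trbv1 by 3.75 ± 0.22 (adjusted p = 1.23e-13), Ccr9 by 1.83 ± 0.22 (adjusted p = 1.56e-06) and Itgb7 by 1.67 ± 0.25 (adjusted p = 4.66e-05). Within set 2 these were 4.59, 3.68, 1.88 and 1.77. Rag1 fell by 4.14 (SE 0.29, adjusted p = 1.07e-11), Cmah, which makes a form of sialic acid, by 3.66, and Pou2af1 by 3.46. The B lineage list had 8 of 22 members lower and 1 higher (Bst1, 2.87), or 10 and 1 adjusted over the list alone (camera adjusted p = 5.04e-14, and 0.00533 with an estimated correlation). Of the Notch list 3 of 15 members were higher and 0 lower, also adjusted over the list alone: Deptor at 2.06, Rgs1 at 1.79 and Nrarp at 1.17 (camera adjusted p = 0.00461; adjusted p = 0.0542 with an estimated correlation). The homing list had Ccr9 and Itgb7 higher, 2 of 16 and 0 lower, also adjusted over the list alone (camera adjusted p = 0.0217, and 0.0332 with an estimated correlation), with a mean of 0.26 and a median of -0.01. Its adjusted p was 0.0775 without CLP replicate 4 and 0.0509 without ETP replicate 5. The cell cycle list had 1 of 28 members higher, Aurka at 1.19, and 0 lower, also adjusted over the list alone (median 0.23, and 0.24 within set 2, camera adjusted p = 2.11e-07, and 0.00474 with an estimated correlation). The T lineage list had Thy1 higher (2.12) and Rag1 lower among 22 members, or 1 and 2 adjusted over the list alone, with no call (camera adjusted p = 0.811). Its median was -0.06 and its mean -0.12, while the test pointed up.

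Granulocyte and monocyte genes were lower in ETP than in CLP in 3 of 23 members and higher in 0, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.000558, and 0.0181 with an estimated correlation), with Irf8 at -2.20 and Ly86 at -1.51. The alarmin genes S100a9 (-4.59 ± 1.11, adjusted p = 0.0138) and S100a8 (-3.50 ± 0.90, adjusted p = 0.0247) and the stefin Stfa3 (-3.38 ± 0.85, adjusted p = 0.0189) were lower. The CLP arrays differed widely, S100a9 standing at 11.76, 10.38, 9.22 and 6.88. Within set 2 the adjusted p-values were 0.053, 0.13 and 0.0484. Leaving out CLP replicate 1 took the S100a9, S100a8 and Stfa3 p-values to 0.0962, 0.172 and 0.132, and leaving out CLP replicate 2 to 0.0581, 0.0958 and 0.084. In all 253 genes were called, 150 higher and 103 lower, or 113 and 133 without the set term, and 230 within set 2. Over the whole profile the distance from ETP to CLP was 0.475 and to LSK 0.436, and the difference of 0.0395 was not past the threshold (exact two-sided permutation p = 0.114 over 35 splits of the 7 marrow arrays). With the spread within CLP and within LSK taken off, an alternative chosen after the data were seen, the mean squared distance was 0.127 to CLP and 0.134 to LSK (exact p = 0.571).

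**Figure D4:**
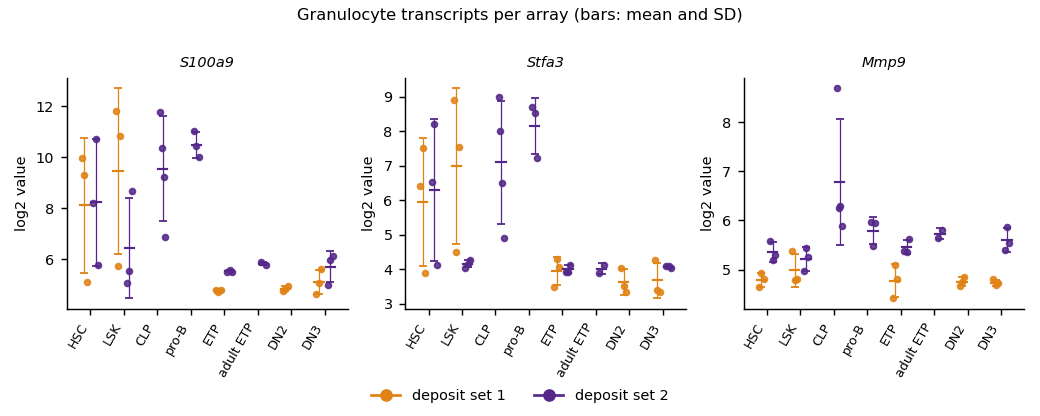
Dots are single arrays (vertical axis, log2 value) by population (horizontal axis), with the mean and SD in each deposit set. S100a9 runs from 6.88 to 11.76 over the CLP arrays and from 5.51 to 5.58 over the ETP arrays of set 2.

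DN2 thymocytes follow ETP, and the comparison asked what changes at that step. The T lineage list rose. Cd3g, a chain of the T cell receptor complex, was higher by 7.78 ± 0.32 (adjusted p = 1.25e-18). It stood at 12.27 ± 0.21 (SD, n = 3) against 4.26 ± 0.46 (n = 3) in set 1. Bcl11b, the T lineage commitment factor, rose by 7.22 ± 0.25 (adjusted p = 1.89e-20). The interleukin 2 receptor Il2ra, which marks DN2, rose by 6.95 ± 0.24 (adjusted p = 3.15e-20) and Gzma, a granzyme, by 6.21 ± 0.26 (adjusted p = 3.91e-18). The T lineage list had 14 of 22 members higher and 0 lower, also adjusted over the list alone (camera adjusted p = 1.37e-51, and 5.5e-08 with an estimated correlation), Cd3e (5.35) and Ptcra (3.81) among them. At the same step Flt3 fell by 5.66 (SE 0.27, adjusted p = 1.06e-16), but ETP were sorted for high Flt3. Hmga2, a chromatin protein of fetal and neonatal stem cells, fell by 5.95 (SE 0.23, adjusted p = 2.4e-19) and Csf1r by 5.91 (SE 0.56, adjusted p = 1.99e-09).

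The granulocyte and monocyte list had 8 of 23 members lower in DN2 and 0 higher, also adjusted over the list alone (camera adjusted p = 2.06e-09, and 0.000228 with an estimated correlation), including Cd33 (-3.38) and the cytokine receptor subunit Csf2rb (-2.49). Of the Notch list 5 of 15 members were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 2.26e-07, and 0.00118 with an estimated correlation). Of the 5, Bcl11b, Il2ra and Ptcra also belong to the T lineage list, and Notch3 rose by 2.56 while Rgs1 fell by 3.64. Natural killer and innate lymphoid genes had 2 of 15 higher (Gzma and Fcer1g) and 2 lower (Il18r1 at -2.71 and Klrd1), also adjusted over the list alone, with no call (camera adjusted p = 0.387). Of the B lineage list 3 of 22 were higher (Pou2af1 4.11, Rag1 3.78, Ly6d 2.46) and 1 lower (Ighm -1.81), also adjusted over the list alone (camera adjusted p = 0.0319, and 0.0678 without DN2 replicate 3; adjusted p = 0.45 with an estimated correlation). In all 562 genes were called, 262 higher and 300 lower, or 289 and 274 with each array centred and 270 and 262 without DN2 replicate 1, and 492 within set 1, which alone holds both populations.

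Between DN2 and DN3 the comparison followed the next thymic stage. Lef1, a partner of beta-catenin, was higher in DN3 by 4.05 ± 0.23 (adjusted p = 6.78e-14), at 11.62 ± 0.21 (SD, n = 3) against 7.23 ± 0.32 (n = 3) in set 1. The lymphoid factor Ikzf3 was higher by 4.13 ± 0.34 (adjusted p = 2.52e-10) and Ptcra, the pre-T cell receptor alpha chain, by 3.14 ± 0.31 (adjusted p = 9.1e-09). Cpa3, a mast cell protease, fell by 5.42 (SE 0.24, adjusted p = 4.33e-17), the homeobox factor Hhex by 4.61 (SE 0.16, adjusted p = 1.65e-19) and Lyl1, a bHLH factor of progenitors, by 4.10 (SE 0.26, adjusted p = 6.27e-13). Of the gate genes, Kit was lower by -1.83 ± 0.29 (adjusted p = 5.12e-05, and 0.059 without the set term) and Cd44 by -2.38 ± 0.19 (adjusted p = 8.61e-11). The T lineage list had 7 of 22 members higher and 0 lower, also adjusted over the list alone (camera adjusted p = 2.67e-07, and 0.0143 with an estimated correlation), with Cd3d at 2.97 and Cd28 at 2.69.

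The Notch list had 3 of 15 members higher (Ptcra, Notch3 1.22, Dtx1 1.02) and 2 lower (Deptor -2.23, Nrarp -1.30), also adjusted over the list alone, with no call (camera adjusted p = 0.55). Granulocyte and monocyte genes had 3 of 23 lower and 0 higher, also adjusted over the list alone: the adaptor Tyrobp (-3.51), Mpo (-3.38 ± 0.82, adjusted p = 0.0607 within set 1) and Anxa1 (-2.13). That list had a median of 0.04, a mean of -0.39 and a downward test (camera adjusted p = 0.0217, and 0.0554 without DN3 replicate 2; adjusted p = 0.114 with an estimated correlation). Natural killer and innate lymphoid genes had 2 of 15 lower, Fcer1g (-1.67) and Nkg7 (-1.33, and -0.98 within set 1), and 0 higher, also adjusted over the list alone (median 0.05, mean -0.18, camera adjusted p = 0.254). Without the genes of low mean that list's median was -0.69 (camera adjusted p = 0.0736). The cell cycle list was lower as a group (median -0.35, camera adjusted p = 5.37e-06, and 0.0115 with an estimated correlation) although 0 of its 28 members were called, over all genes or adjusted over the list alone. Top2a stood at -0.65 (adjusted p = 0.00412) and Rrm1 at -0.54 (adjusted p = 0.00821), both under 2-fold. In all 426 genes were called, 140 higher and 286 lower, and 416 within set 1. There were 276 genes called with these 2 populations alone in the model and no set term, where Kit, Fcer1g and Nkg7 lost their calls (adjusted p = 0.205, 0.0556 and 0.0837).

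Pro-B cells were set against CLP to describe the B cell path from the marrow progenitor. Igll1 was higher by 6.23 ± 0.31 (adjusted p = 1.83e-15), at 12.54 ± 0.08 (SD, n = 3) against 6.31 ± 0.12 (n = 4), and Spib, an Ets factor, by 4.29 ± 0.34 (adjusted p = 4.54e-11). The B lineage list had 18 of 22 members higher and 0 lower, also adjusted over the list alone (camera adjusted p = 3.17e-24, and 0.000333 with an estimated correlation), with Pax5, the B lineage commitment factor, at 3.54, and Cd79a at 3.40. Cd34, a surface protein of progenitors, fell by 5.77 (SE 0.24, adjusted p = 2.1e-17), Cd27 by 3.89 (SE 0.26, adjusted p = 9.85e-13) and Kit by 1.39 (SE 0.30, adjusted p = 0.0011). The early lymphoid list had 5 of 16 lower, Flt3 at -2.85 among them, and 1 higher, Ikzf3 at 3.45, also adjusted over the list alone (camera adjusted p = 3.43e-05, and 0.000865 with an estimated correlation). Cell cycle genes had 14 of 28 higher and 2 lower, or 15 and 2 adjusted over the list alone (camera adjusted p = 1.28e-08, and 0.002 with an estimated correlation). The mitotic kinases Plk1 (1.99) and Aurka (1.98) rose and the replication helicase subunits Mcm4 (-1.96) and Mcm6 (-1.44) fell.

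Granulocyte and monocyte genes had 5 of 23 lower in pro-B and 1 higher, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.00388, and 0.0452 with an estimated correlation), with Mpo at -5.00 ± 0.85 and Tyrobp at -2.91 ± 0.26. Of the T lineage list 3 of 22 were higher (Spib, Lef1 4.17, Thy1 2.12) and 1 lower (Lat -1.28), also adjusted over the list alone, with no call (camera adjusted p = 0.351). Late granulocyte transcripts averaged 6.14 and 6.06 on pro-B replicates 1 and 2 and 6.86 and 5.72 on CLP replicates 1 and 2. Without the 7 marrow arrays with such transcripts, these 4 among them, 1 pro-B array was left, too few to count called genes. That array, replicate 3, still had a late granulocyte mean of 5.30, against at most 4.84 on the thymic arrays of set 2. The pro-B arrays were also low in Y-linked transcripts: Kdm5d differed by -4.29 (adjusted p = 3.22e-06) and Eif2s3y by -3.52 (adjusted p = 2.3e-05). Xist differed by -0.91 (adjusted p = 0.00229). The sex of the mice may thus differ between the pro-B and CLP arrays, and which calls belong to it was not tested. In all 1064 genes were called, 605 higher and 459 lower. After quantile normalization over all arrays the split was 548 higher and 648 lower.

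The adult ETP arrays were set against the other ETP, as their titles name them adult although every age label reads 1 week. The largest difference was in Xist, the transcript that silences an X chromosome in females. It was lower by a log2 difference of -6.56 ± 0.23 (adjusted p = 2.14e-19), standing at 5.46 ± 0.47 (SD, n = 2) against 12.06 ± 0.08 (n = 3) in set 2. The fetal and neonatal list had 2 of 12 members lower and 0 higher, also adjusted over the list alone: Hmga2 (-1.26 ± 0.26, adjusted p = 0.0204) and the RNA-binding Igf2bp3 (-1.26 ± 0.22, adjusted p = 0.00718), each at -1.31 and -1.30 within set 2 (adjusted p = 0.015). The list was not called (camera adjusted p = 0.0661), but it was called lower within set 2 (0.0122), after quantile normalization (0.0212), without the genes of low mean (0.0027) and without adult replicate 2 (0.0336). Dntt was higher by 1.93 ± 0.34 (adjusted p = 0.00718) and by 1.55 within set 2 (adjusted p = 0.015), and Fasl lower by -1.74 ± 0.30 (adjusted p = 0.00718) and by -1.59 within set 2 (adjusted p = 0.04). The heat shock genes Hspa1b (4.14 ± 0.83) and Hspa1a (3.97 ± 0.65) were called higher. They stood at 11.22 and 10.01 on adult replicate 1 against 7.07 and 4.63 on replicate 2, and within set 2 the adjusted p-values were 0.232 and 0.127.

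**Figure D5:**
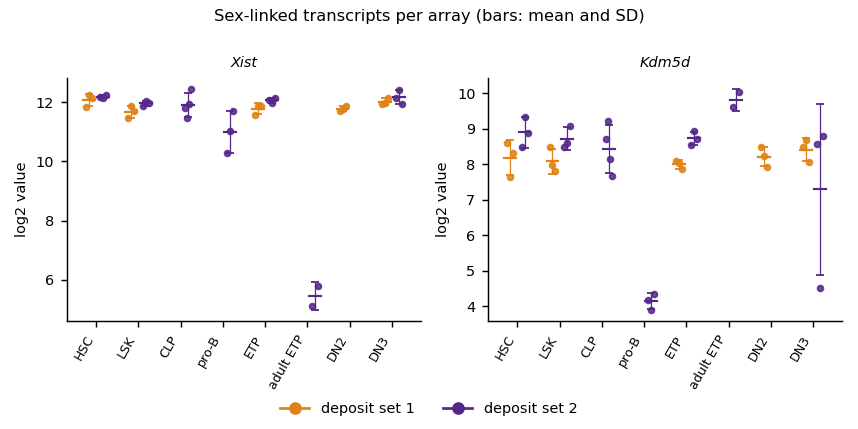
Dots are single arrays (vertical axis, log2 value) by population (horizontal axis), with the mean and SD in each deposit set. Xist is at 5.13 and 5.80 on the adult ETP arrays and above 10 on all other arrays, and Kdm5d is at 3.90 to 4.36 on the pro-B arrays.

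No member of the T lineage (22) or cell cycle (28) lists was called between adult and other ETP, over all genes or adjusted over the list alone. The cell cycle list was lower as a group (median -0.26, camera adjusted p = 0.000156, and 0.0321 with an estimated correlation), with Ccna2 at -0.76 (adjusted p = 0.0881), and the T lineage list was not called (camera adjusted p = 0.575). Of 23 granulocyte and monocyte genes 0 were called, or 1 higher adjusted over the list alone, Lyz2 standing at 1.11 with adjusted p = 0.107 over all genes (camera adjusted p = 0.6). Of the B lineage list 1 of 22 was lower, Bst1 at -1.78 (adjusted p = 0.0489, and 0.146 within set 2), also adjusted over the list alone (camera adjusted p = 0.575). In all 38 genes were called, 11 higher and 27 lower, or 29 and 33 after quantile normalization. There were 13 genes called within set 2, 6 without adult replicate 1, 23 without adult replicate 2 and 20 without ETP replicate 6. Of the named genes, Xist alone kept its call without adult replicate 1 and with these 2 populations alone in the model and no set term. Without adult replicate 2 the calls of Dntt (0.0833), Hmga2 (0.129) and Bst1 (0.234) were lost as well, and without ETP replicate 6 those of Hmga2 and Hspa1b (each 0.0533). Leaving out ETP replicate 1, 2, 3, 5 or 6 took Bst1 to 0.0671 to 0.0758. With all arrays and no set term Hmga2 and Bst1 were at adjusted p = 0.212 and 0.261.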

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

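The tests on splits of the arrays into called genes, and the test on scatter between the CLP arrays, were chosen only after the result was seen; those on whole-profile distance, granule genes and Y-linked genes were set beforehand.

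Cd48 differed between the deposit sets in LSK minus HSC, by 6.84 in set 1 and 4.21 in set 2, a difference of 2.63 on the log2 scale (interaction adjusted p = 0.0154). HSC replicate 5, where Cd48 stood at 7.47, was also the HSC array with the highest late granulocyte mean, 6.13. Of 199 groups of arrays tested for 1 array far from the others, 2 had one, where chance gives about 5% of groups. They were Fam72a at 5.24 on CLP replicate 3 and Mmp9 at 8.69 on CLP replicate 1.

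CLP and LSK differed in 60 called genes, fewest of the 7 comparisons with at least 3 arrays a side. Scatter between the CLP arrays stays open as a reason: the same 4 arrays gave 253 called genes against ETP and 1064 against pro-B, but larger true differences would give that too. The test set beforehand came out as it would if the arrays of set 2 held the same cells: the ratio of between-population to within-population distance was 1.05, 5 of 35 splits reached it (a share of 0.143), and the highest other was 1.10. The test chosen afterwards spoke against the same cells handled alike: within set 2 only the real split, 1 of 35, called as many as 59 genes, the highest other calling 17. A closely related cell state that divides less may account for the called genes. A difference of day or handling between the populations was not tested and stays open. As a list, immediate early and heat shock genes hardly differed within set 2, which holds all CLP arrays (median -0.058). Of its members Fos was lower there, at 7.93 ± 1.84 (SD, n = 4) in CLP against 9.74 ± 0.31 (n = 3) in LSK. Fosb (5.42 ± 1.69 against 7.17 ± 0.72), Jun (9.25 against 10.09) and Dusp1 (8.79 against 9.2) were lower too. Egr1 (8.69 against 8.67), Hspa1a (3.17 in both) and Hspa1b (3.69 against 3.73) hardly differed. Over both sets the list's median was -0.66 (camera adjusted p = 3.74e-05, and 0.205 with an estimated correlation). That value also takes in the LSK arrays of set 1, so by itself it is no sign of such a difference. The lower Fos, Fosb and Jun within set 2 leave such a difference open.

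S100a8, S100a9, Stfa3 and Mmp9 were higher in CLP than in LSK of set 2 by 2.58, 3.12, 2.94 and 1.56, of which Mmp9 alone was called in the full fit. A candidate source is mature granulocytes, which a sort for lineage-negative cells, as the LSK gate is by name, would remove; 7 late granulocyte genes had a median difference of 0.93 (median SE 0.59, from 0.18 to 1.70), between the bounds of 0.3 and 1 set for this test. A stronger granulocyte and monocyte progenitor programme needed Elane, Prtn3 and Ctsg to be higher, and their median was 0.25 (median SE 0.25), within its SE of the lower bound; all 3 also belong to the granulocyte and monocyte list, as does Ltf of the other 7. In set 2 S100a9 reached 11.76 on CLP replicate 1 and 11.03 on pro-B replicate 1, against 5.01 to 6.14 on the thymic arrays, and in set 1 11.81 on LSK replicate 1 against 4.66 to 5.61. The tests could not tell the 2 sources apart, because the spread between the 4 CLP arrays is wide (Ngp ran from 5.40 to 8.85). On CLP replicates 1 to 4 S100a9 was 11.76, 10.38, 9.22 and 6.88, and the late granulocyte mean 6.86, 5.72, 4.79 and 4.89. Prtn3 (6.10, 6.22, 7.12 and 6.83) and Ctsg (5.01, 6.06, 6.14 and 6.46) were lowest on replicate 1, against a stronger progenitor programme there. Elane (4.28, 4.10, 4.15 and 4.07) was highest on replicate 1. It lay below the lower quartile of every set 2 array (4.41 to 4.67), so its order says little.

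Xist was lower in the adult ETP arrays by -6.59 within set 2, at 5.13 and 5.80 against 11.97 to 12.12. Adult arrays made from male mice alone may account for this: the 3 measured Y-linked genes, Eif2s3y, Kdm5d and Uty, were higher than in ETP of set 2 by a median of 0.84 (median SE 0.24, from 0.68 to 1.09), above the bound of 0.3 set for this test. In the full fit none of the 3 was called, Kdm5d standing at 1.34 with adjusted p = 0.335. The labels give both sexes for every array, and age and sex then go together in these 2 arrays, so which of the other differences belongs to which was not tested. Y-linked transcripts were near the floor on the pro-B arrays (Kdm5d 3.90 to 4.36) and on DN3 replicate 5 (4.52); the arrays other than these and the adult ones carried both Xist and Kdm5d.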

How the results depend on the processing

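The tests without the arrays holding late granulocyte transcripts, and that of squared distance less the spread within groups, were chosen only after the result was seen. The distance from ETP to CLP less that to LSK turned to -0.011 over the 1000 most variable genes (exact p = 0.886) and to -0.0069 as squared distance less the spread within groups (exact p = 0.571). Of 16 alternatives 9 could pass the threshold and 0 did (exact p from 0.114 to 0.886). The other 7, without a CLP or an LSK array, have too few splits, with smallest p-values of 0.1 and 0.0667. With 1 array left out the difference in distance itself, not its p, was 0.029 to 0.054 on the log2 scale. The alternatives other than leaving out an array gave 1874 values of named genes. Of these 1787 kept their call or lack of a call, 83 lost the call and 4 gained it. Of 1447 values with 1 array left out, 1397 kept their call or lack of a call and 50 lost the call. A value uncalled both before and after was counted as kept even where its sign turned. Where a cause is not named, the cause was not tested.

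Counts of called genes stayed within 1.5 times under 83 of 107 alternatives and 74 of 77 omissions. Without the set term CLP minus LSK called 38 and adult minus other ETP 14. With only the compared populations in the model the counts were 11 for CLP minus LSK, 276 for DN3 minus DN2 and 2 for the adult arrays. This also drops the set term in these 3 comparisons, so 2 choices changed together. Quantile normalization gave 62 for the adult arrays, array weights 133 and set 2 alone 13. Without a fold threshold, which by construction calls more, the counts in the order of the plot of counts were 4749, 104, 637, 502, 934, 1114, 3097 and 80. Testing against 1.5-fold with treat gave 7 for CLP minus LSK, 149 for ETP minus LSK, 95 for ETP minus CLP, 292 for DN2 minus ETP, 157 for DN3 minus DN2, 419 for pro-B minus CLP and 2 for the adult arrays. Only genes chosen by the rule for named genes were followed under this test, and others named in the text were not. Of those followed it left Aspm, Prc1, Fam72a, Igll1 and Mmp9 uncalled in CLP minus LSK, Nrarp and Csf1r in ETP minus LSK, and S100a8, S100a9, Stfa3, Ly86 and Rgs1 in ETP minus CLP. It also left out Mpo and Nkg7 in DN3 minus DN2, Kit in pro-B minus CLP, and all but Xist and Hspa1a of the adult comparison. Without the arrays holding late granulocyte transcripts pro-B minus CLP called 421, with 1 pro-B array left, and CLP minus LSK 42, 33 of them shared. Leaving out 1 array gave 6 to 40 for the adult arrays, the 3 that moved the count being adult replicate 1 (6), adult replicate 2 (23) and ETP replicate 6 (20). The other ranges were 1501 to 1570 for LSK minus HSC, 49 to 63, 282 to 303, 213 to 260, 497 to 559, 360 to 458 and 856 to 1386 in the same order.

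Of 430 list values under alternatives other than leaving out an array, 16 lost the call, 6 gained it, 16 turned sign with a call before or after, and the others kept theirs; of 385 with 1 array left out these were 12, 1 and 13. For homing in ETP minus LSK the median was 0.12 without the genes of low mean (camera adjusted p = 0.0193) and 0.053 within set 2 (0.0108), both called higher. For homing in ETP minus CLP they were 0.00433 with centred arrays, 0.092 with the mean of probe sets, 0.10 with the most variable probe set, 0.31 without the genes of low mean, 0.035 within set 2, and -0.059 to 0.092 with 1 array left out. The B lineage list stood at 0.18 in CLP minus LSK and -0.38 in DN2 minus ETP, both without the set term and with only the compared populations, where the sets are not set apart. The Notch list in ETP minus CLP was -0.079 with the mean of probe sets. In DN3 minus DN2 the granulocyte and monocyte list was -0.18 with quantile normalization, -0.063 with the most variable probe set, -0.063 without the genes of low mean, -0.064 within set 1 and -0.13 to 0.11 with 1 array left out.

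Label numbers recur across populations, and they did not pair the arrays: of 21 pairs with the same number in a set, 1 had a correlation of deviations over 0.1. With the replicate block the counts were 1526 for LSK minus HSC, 303 for ETP minus LSK, 552 for DN2 minus ETP, 422 for DN3 minus DN2 and 1072 for pro-B minus CLP, and 119 of 119 named genes and lists kept their call. Signal near background limits the low genes: the lower quartile of an array lay at 3.55 to 3.65 in set 1 and 4.41 to 4.67 in set 2.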

Other observations

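The tests of lists between the deposit sets, and those on splits of the arrays, were chosen only after the result was seen. Genes are named here after their values were seen. The B lineage list was already higher in LSK than in stem cells: 13 of 22 members were higher and 0 lower, also adjusted over the list alone, with Ighm at 4.17 and Ebf1, a B lineage factor, at 3.59 (camera adjusted p = 7.42e-11, and 0.0143 with an estimated correlation). In ETP the early lymphoid list was lower than in LSK, with 6 of 16 members lower and 0 higher, also adjusted over the list alone (camera adjusted p = 4.13e-14, and 4.58e-07 with an estimated correlation). Natural killer and innate lymphoid genes had 3 of 15 higher in ETP than in LSK, Il18r1 at 1.58, Nkg7 at 1.39 and Gzma at 1.28, and Fcer1g lower, also adjusted over the list alone (camera adjusted p = 0.00689, and 0.0143 with an estimated correlation). Between ETP and DN2 the homing list fell, with 6 of 16 lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.000207, and 0.00142 with an estimated correlation); Ccr9 fell by 3.35 and Cd44 fell by 2.28, while Itga4 rose by 1.25. Ccr9 was higher again in DN3 than in DN2, by 1.54.

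Of genes of double-positive thymocytes, 4 of 9 were higher in DN2 than in ETP and 0 lower, or 4 and 1 adjusted over the list alone, with Themis at 6.06 and Tcra at 2.04 (camera adjusted p = 3.68e-08, and 3.13e-05 with an estimated correlation). Dendritic cell genes had 2 of 16 lower in DN2 and 0 higher, also adjusted over the list alone: Cd74 at -1.56 and Ccr7 at -1.29 (camera adjusted p = 0.000763, and 0.00897 with an estimated correlation). Immediate early and heat shock genes had 5 of 16 lower in ETP than in LSK and 0 higher, or 9 and 0 adjusted over the list alone, with Fos at -3.65 and Egr1 at -3.42 (camera adjusted p = 2.71e-10, and 0.0404 with an estimated correlation). That list's median was -1.72 within set 1 and -0.45 within set 2. In LSK minus HSC it had 4 of 16 lower and 0 higher, or 6 and 0 adjusted over the list alone. Its median there was -0.82, with -0.25 within set 1 and -1.32 within set 2 (camera adjusted p = 0.00545, and 0.42 with an estimated correlation). In DN2 minus ETP it had 1 of 16 lower and 0 higher, also adjusted over the list alone (median -0.69, camera adjusted p = 0.00398, and 0.407 with an estimated correlation). In CLP minus LSK it had 0 of 16 members called, or 3 lower adjusted over the list alone, with Fosb at -2.89 (adjusted p = 0.152) and Fos at -2.45 (adjusted p = 0.228); its median was -0.66, and -0.058 within set 2 (camera adjusted p = 3.74e-05; adjusted p = 0.205 with an estimated correlation). In the adult arrays 3 of its members were higher, or 4 adjusted over the list alone (camera adjusted p = 1.27e-07; adjusted p = 0.0911 with an estimated correlation).

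Stroma and endothelium genes had 5 of 14 lower in LSK than in HSC and 0 higher, also adjusted over the list alone, with Sparc at -3.76 (camera adjusted p = 0.00496; adjusted p = 0.273 with an estimated correlation). Macrophage genes had 1 of 14 higher and 2 lower there, also adjusted over the list alone (camera adjusted p = 0.44). Thymic epithelium genes had 1 of 13 higher in DN3 than in DN2, Epcam at 1.34, also adjusted over the list alone (camera adjusted p = 0.0323; adjusted p = 0.256 with an estimated correlation). Red cell genes had 2 of 7 lower in ETP than in CLP, Slc4a1 at -2.65 and the globin Hbb-b2 at -2.01, also adjusted over the list alone (camera adjusted p = 0.0242; adjusted p = 0.181 with an estimated correlation).

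Further lists not set for a comparison beforehand passed at both correlations. Against CLP, ETP had 4 of 16 early lymphoid genes lower and 0 higher, or 5 and 0 adjusted over the list alone (camera adjusted p = 1.62e-10), and 1 of 16 dendritic cell genes higher, Cd74 at 1.10, also adjusted over the list alone (0.00652). Between ETP and DN2 4 of 16 early lymphoid genes were lower and 2 higher (0.00103), and 1 of 12 fetal and neonatal genes lower, Hmga2 (0.00349), both also adjusted over the list alone. Pro-B cells had 2 of 16 homing genes lower than CLP, Ccr9 at -1.05 and Cd44 at -1.11, also adjusted over the list alone (0.0112). The list of double-positive thymocytes, which holds Rag1, was higher in LSK than in HSC (median 0.16, 0.000201) and in DN3 than in DN2 (0.56, 0.000156), and lower in ETP than in LSK (-0.32, 7.99e-07) and CLP (-0.15, 0.000125).

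Several lists shifted between the deposit sets: of 72 tests 22 passed at the preset correlation and 15 also with an estimated one. From set 1 to set 2 the median of the B lineage list moved by 0.67 more in LSK than in HSC (camera adjusted p = 4.95e-10, and 0.00388 with an estimated correlation) and by 1.18 more than in DN3 (camera adjusted p = 4.97e-17, and 0.000187 with an estimated correlation). Of its 22 members 3, 2 and 6 were called for such a shift in LSK against HSC, ETP and DN3. In ETP against HSC its shift was 0.06 (camera adjusted p = 0.423). Pax5 in LSK stood at 5.53 ± 0.46 (SD, n = 3) in set 1 and 8.56 ± 0.33 (n = 3) in set 2, against 4.99 and 5.79 in HSC. Stroma and endothelium genes moved by -0.68 in LSK against HSC (camera adjusted p = 5.26e-09, and 0.0106 with an estimated correlation) and by -0.62 in ETP against HSC (camera adjusted p = 2.15e-07, and 0.0216 with an estimated correlation). Macrophage genes moved by -0.35 and -0.40 in the same 2 pairs (0.0016 and 0.00547 with an estimated correlation), and stem cell genes by 0.56 in ETP against HSC (0.0246). Against ETP, LSK also moved in stem cell (-0.29), megakaryocyte and erythroid (-0.23) and granulocyte and monocyte genes (-0.25), at 0.0327, 0.0216 and 0.0143 with an estimated correlation. Against DN3 it moved in T lineage (0.55), Notch (0.46), stem cell (-0.52) and immediate early genes (-2.17), at 0.000123, 0.0264, 0.0106 and 0.0216. Immediate early genes also moved by -0.82 against HSC and -0.96 against ETP (camera adjusted p = 1.69e-05 and 2.15e-07; adjusted p = 0.153 and 0.0784 with an estimated correlation). Of single genes, 74 were called for a difference between the sets in LSK minus HSC, and 6 in ETP minus LSK. In 62 of the 74 the signed log2 difference was higher in set 1. The lower quartiles of the arrays were 3.55 to 3.65 in set 1 and 4.41 to 4.67 in set 2. A gene near background in 1 population can thus differ less in set 2, and how many of the 74 do so was not tested.

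Other splits of the arrays were counted for the 7 comparisons with at least 3 arrays a side, and in each the real split, 1 of those run, called the most genes, but the splits of 6 of them mix arrays of the 2 sets, which were normalized apart. Of 100 splits each, the real and the highest other count were 1530 and 888 for LSK minus HSC, 60 and 11 for CLP minus LSK, 303 and 84 for ETP minus LSK, and 253 and 30 for ETP minus CLP. Of 84 splits each they were 562 and 72 for DN2 minus ETP and 426 and 221 for DN3 minus DN2, where 35 of the other splits called at least 1 gene. Of 35 splits they were 1064 and 550 for pro-B minus CLP, all in set 2. With arrays exchanged within a set, the highest other counts of 100 splits were 760 for LSK minus HSC and 62 for ETP minus LSK. Of 35 splits they were 6 for CLP minus LSK and 2 for ETP minus CLP. Only the real split, 1 of those run, reached its count in these 4 and in pro-B minus CLP. The share was 0.01 with 100 splits and 0.0286 with 35, the smallest that so many splits allow. These shares were not adjusted over the comparisons, so they make chance unlikely without excluding it. For DN2 minus ETP and DN3 minus DN2 there are 20 such splits, too few for a share under 0.05, and the highest others were again 72 and 221.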
